A study of Mus musculus with 6 samples.

How the data were processed

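Gene expression was measured by RNA sequencing in mouse lenses at embryonic day 13.5, in 3 libraries from a conditional knockout of the transcription factor gene Prox1 and 3 libraries from wild type C57Bl/6 lenses. The knockout carried floxed Prox1 alleles and the MLR10-Cre transgene, which is active in lens cells. Each library is a biological replicate made from a pool of 30 lenses, per the labels. The libraries were made with a TruSeq RNA kit that selects polyadenylated RNA and keeps no strand, and were sequenced as single-end reads of 51 bp. Reads of genes that overlap on opposite strands can therefore not be assigned to one of them. Which exon of Prox1 was floxed is not given in the sources used here. Nothing in the labels says whether lenses of the same litters or embryos entered more than 1 pool, so p-values measure the spread between these pools.

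Each of the 6 deposited tables lists 41128 features with a raw count, a CPM and an RPKM. Per the file headers, the first value is a raw count per feature, and all values tested were whole numbers with a different total per library. The deposited CPM equals the raw count scaled by the library's total alone, within 1e-06, without TMM factors. Which scaling the authors' own comparison used is not shown by the files. The RPKM made by the authors equals CPM divided by 1 length per feature, which the tables do not list. It is missing for 11976 features, none of which has a count, and infinite for 1 feature. Genome build GRCm38 and edgeR are named per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. In 26 features, 24 of them in pairs whose names differ only in upper and lower case and 2 others numbered as copies of Supt20, the count and the CPM belonged to different members of the pair. These 26 features were left out because the files cannot say which value belongs to which gene, and they held between 0.0424% and 0.0636% of the counts of a library. Of all 41128 features, 19852 had no count in any library. Of the 41102 features kept, 37988 matched a gene of the GENCODE mouse release 21 annotation of the same build, which gave coordinates. The match was by the Ensembl identifier listed with the feature or, where that was not in the annotation, by name. RPKM values were not used here.

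The raw counts were analysed in R 4.3.3. Features were kept for testing by the edgeR function filterByExpr with the groups given and a minimum count of 10, library sizes were scaled by TMM, and the knockout was compared with the wild type by the edgeR 4.0.16 quasi-likelihood test with no other term in the model. Adjusted p-values are Benjamini-Hochberg values over all features tested, with a threshold of 0.05, and changes of at least 2-fold were counted beside them. Log2 fold changes are knockout minus wild type with a standard error (SE), and levels are CPM scaled by TMM, as mean ± SD with n = 3 libraries per group. Log2 CPM values for list tests and principal components used a prior count of 2. A count of 3 was taken as the level that a count of 0 allows, which corresponds to between 0.106 and 0.33 CPM in the 6 libraries and covers counting error only.

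There were 13 lists of genes of lens biology and signalling and 9 lists of markers of other cell types. They were crystallins, lens fibre genes other than crystallins, lens epithelium, lens transcription factors, FGF receptors and feedback, the Notch pathway, CDK inhibitors, proliferation, p53 and apoptosis, cell adhesion and cytoskeleton, extracellular matrix, mesenchymal transition and genes tied to Prox1 in lymphatic endothelium. The marker lists were neural retina, neurons, pigment cells, erythroid cells, blood vessel endothelium, macrophages, periocular mesenchyme, surface ectoderm and skeletal muscle. Each list was compared with all other tested genes by camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 22 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run as alternatives. Members were counted at the threshold over all genes and also adjusted over the list alone. Exons shared with other annotated genes were counted from the annotation.

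The genes named were Prox1, the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold, and members of the lists in order of the size of their change. The 20 genes of largest change had to have all knockout libraries on one side of all wild type libraries and a mean of at least 10 CPM in the higher group. Bfsp2, Nnt, Wdfy1, Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were fixed as checks of strain and of the pools. The comparison, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes outside the rule are named as chosen after their values were seen.

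The alternatives were DESeq2 size factors, upper quartile scaling, scaling without crystallin counts, no filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block and leaving out each library in turn. A pair of further settings was added after the data were seen, one without knockout library 3 and wild type library 1 together and one without the genes Lars2 and Gm26917. The fit was tested on simulated data with the dispersions and depths of these libraries, 14271 genes and 200 changed genes. It recovered 38.2% of the genes changed 1.5-fold, 67.2% of those changed 2-fold and 86.4% of those changed 4-fold, and 13 of 137 calls were false. Camera called a list of 20 simulated genes raised 1.5-fold, and it called 5 of 100 unchanged lists at the same threshold. The simulated genes were drawn independently of one another, so that rate does not cover lists whose members are correlated. The 200 changed genes are also far fewer than the 4659 called in the real comparison, so the recovered shares do not carry over to it directly.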

Results

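Expression was compared between 3 libraries of Prox1 conditional knockout lenses and 3 libraries of wild type lenses at E13.5, a stage at which primary lens fibre cells elongate and build up crystallins. The totals were 28391662, 10907877 and 9082219 counts in knockout libraries 1, 2 and 3 and 21061582, 20731491 and 20812141 counts in wild type libraries 1, 2 and 3. The 16 crystallin genes took 2.94 ± 0.169% of the counts in the knockout and 19.1 ± 5.18% in the wild type (SD, n = 3 each). Wild type library 1 held 13.2% crystallin counts, against 21.5% and 22.7% in the other wild type libraries. The most abundant of these genes, Cryaa, took 1.79 ± 0.124% of the counts in the knockout and 8.5 ± 1.8% in the wild type. Mitochondrially encoded genes took 2.60 ± 0.322% and 2.07 ± 0.276%. A principal component that held 71% of the variance placed the knockout libraries between -53.6 and -39.9 and the wild type libraries at 24.1 for library 1, 59.4 for library 2 and 52.9 for library 3. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.977 and 0.99 for pairs of libraries of the same group.

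Prox1 is the gene targeted in the knockout and encodes a homeodomain transcription factor needed for lens fibre elongation. Its transcript (ENSMUSG00000010175, GRCm38 chromosome 1, 190118035 to 190170714, minus strand) fell by 0.70 on the log2 scale (SE 0.141, edgeR adjusted p 0.0074), which is 1.62-fold. Its level was 695 ± 39.9 CPM in the knockout and 1128 ± 179 CPM in the wild type (SD, n = 3 each). The knockout libraries had 651, 728 and 707 CPM and the wild type libraries 922, 1215 and 1246 CPM. The count covers all exons of Prox1, including any that the Cre recombinase leaves in place. Without 1 library at a time, the log2 change of Prox1 lay between -0.87 and -0.65, with edgeR adjusted p between 0.00124 and 0.0362. The antisense gene Prox1os starts within the Prox1 locus (chromosome 1, 190170296 to 190217276, plus strand) and was chosen after its values were seen. Prox1os fell 13.7-fold (log2 -3.78, SE 0.313, edgeR adjusted p 0.000163), from 66.8 ± 20.7 CPM to 5.03 ± 1.76 CPM. The exons of the pair share 133 bases, 1.6% of those of Prox1 and 16.1% of those of Prox1os.

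The comparison asks which genes differ between knockout and wild type lenses of the embryo. The series has no library with the Cre transgene alone or with floxed alleles alone, and the labels do not give the strain of the knockout. Effects of strain or of the Cre transgene can therefore not be told apart from those of Prox1 loss. Among called genes with at least 10 CPM in the higher group and no overlap between the groups' libraries, the fibre genes Dnase2b, Birc7, Crygf and Bfsp1 had the largest decreases, each at least 39.4-fold, and Calb1, Ppp1r14c, Cngb3 and Tnc had the largest increases. Of 14271 genes tested, 4659 (32.6%) changed past the threshold of the edgeR quasi-likelihood test, 2263 rising and 2396 falling, and 9612 were not called. At an unadjusted p below 0.05 there were 6464 genes. Changes of at least 2-fold were called for 1565 genes, 836 higher and 729 lower. The balance turned without wild type library 2 (427 higher and 621 lower), wild type library 3 (525 and 620) or knockout library 3 (564 and 769). At least 8-fold changes were called for 51 genes that rose and 113 that fell. All knockout libraries lay on one side of all wild type libraries for 7146 genes (50.1%), where chance gives 10%. Without wild type library 2 the count of changed genes was 2267, of which 836 rose and 1431 fell, and without wild type library 3 it was 2475, of which 952 rose and 1523 fell. The count lay between 3355 and 5317 when any other library was left out.

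Calb1, which encodes the calcium-binding protein calbindin, had the largest increase of the genes within these limits (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064). It rose 121-fold (log2 6.92, SE 0.223, edgeR adjusted p 4.63e-06), from 0.419 ± 0.0897 CPM in the wild type to 51.1 ± 9.02 CPM in the knockout (SD, n = 3 each). Tnc, which encodes the matrix glycoprotein tenascin C (chromosome 4, 63959785 to 64047015), rose 30.8-fold (log2 4.94, SE 0.272, edgeR adjusted p 4.42e-05), from 12.4 ± 5.21 to 380 ± 21.3 CPM. The cone channel subunit gene Cngb3 rose 56.3-fold, from 1.38 ± 0.40 to 78.9 ± 9.40 CPM. The phosphatase inhibitor gene Ppp1r14c rose 67.9-fold, to 27.4 ± 5.20 CPM. Hpse, which encodes heparanase, rose 27.2-fold and the signalling regulator gene Rgs6 rose 20.9-fold. The transcription factor gene Sox21 rose 18.5-fold, C1qtnf4 18.2-fold and the glutamate transporter gene Slc1a2 12.1-fold. The prokineticin receptor gene Prokr1 rose from 6.96 ± 2.37 to 93.7 ± 20.5 CPM. Exons of genes on the opposite strand cover 29.2% of the exon bases of Ppp1r14c and 18.8% of those of Sox21, and their reads could not be separated.

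Within the same limits, the genes with the largest decreases included those for a nuclease and a filament protein of differentiating fibre cells. Dnase2b, whose nuclease degrades DNA when fibre cells lose their nuclei, fell 92.4-fold (log2 -6.53, SE 1.32, edgeR adjusted p 0.00731), with 0, 5 and 4 counts in the knockout libraries and 31, 341 and 517 in the wild type libraries. Birc7 fell 71.2-fold, with 4, 2 and 3 counts in the knockout and 35, 231 and 382 in the wild type. Crygf (chromosome 1, 65926520 to 65928307) fell 52.9-fold, from 2744 ± 1790 to 52.5 ± 40.5 CPM (edgeR adjusted p 0.00274). Bfsp1, which encodes the beaded filament protein filensin (chromosome 2, 143826528 to 143863173), fell 39.4-fold, from 1563 ± 1080 to 40.1 ± 17.3 CPM (edgeR adjusted p 0.00112). Crygb fell 38.7-fold, and the channel subunit genes Scn11a and Scnn1b fell 30.8-fold and 23.8-fold. The dopamine receptor gene Drd4 fell 28.9-fold and had a narrow spread in the wild type, 18.3 ± 0.93 CPM. Hopx, with 27.2% of its exon bases shared with the opposite-strand gene Hopxos, fell 26.5-fold, and the noncoding RNA gene Gm20757 fell 25.8-fold. Wild type library 1 was the lowest of the wild type libraries for Dnase2b, Birc7, Crygf and Bfsp1. The fold of Dnase2b depended on single libraries, with a log2 change of -5.33 without knockout library 1 and -5.83 without wild type library 3, and of -7.34, -7.12 and -7.14 without knockout library 2, knockout library 3 and wild type library 1. Without 1 library the log2 change lay between -6.72 and -5.45 for Birc7, between -6.41 and -5.22 for Crygf and between -5.49 and -4.26 for Drd4. All 20 genes of largest change passed the edgeR threshold whichever library was left out. With limma-voom, Dnase2b (adjusted p 0.101) and Birc7 (adjusted p 0.0671) did not pass.

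**Figure D1:**
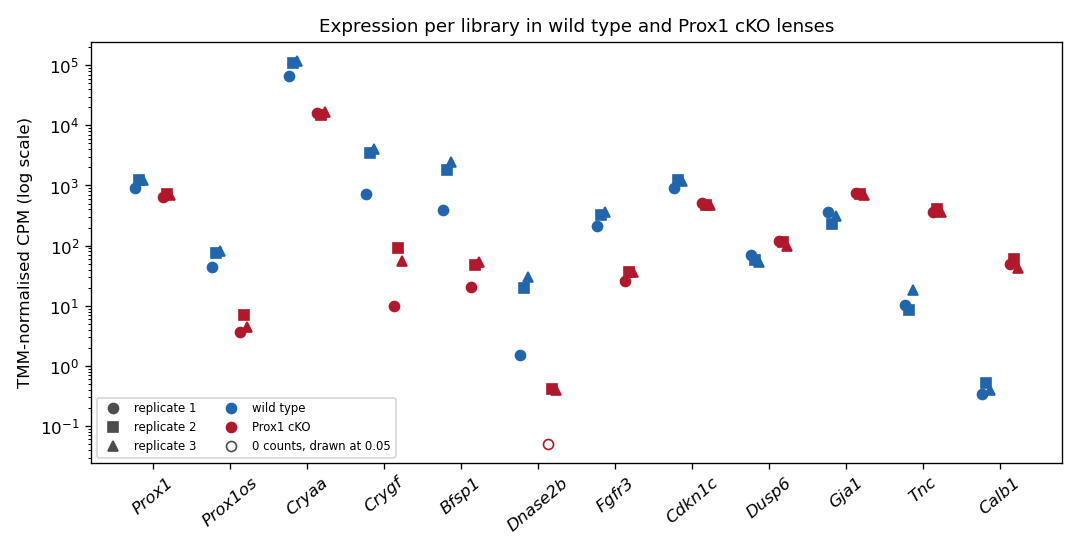
Level of 12 genes in each library, in TMM-scaled CPM on a log axis, for the knockout and the wild type, with circle, square and triangle for replicates 1, 2 and 3 and an open symbol for a count of 0. Calb1 averaged 51.1 CPM in the knockout and 0.419 CPM in the wild type, and Bfsp1 averaged 40.1 and 1563 CPM.

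Crystallins, the soluble proteins that fill lens fibre cells, fell almost as a whole group. Of 16 tested genes, 15 fell and 0 rose by edgeR, DESeq2 and limma-voom alike, with no member rising at an unadjusted p either, and the same numbers held adjusted over the list alone. The median log2 change was -3.81. The largest decreases were those of Crygf, Crygb (from 6110 ± 3540 to 159 ± 94.9 CPM), Crygd (21.5-fold) and Crygs (16.2-fold). Cryaa fell 6.17-fold (edgeR adjusted p 0.000297), from 97580 ± 28100 to 15820 ± 843 CPM, and Crybb1 fell 11.6-fold, from 23540 ± 7810 to 2036 ± 445 CPM. Cryab, which is also expressed outside fibre cells, had a smaller decrease, 2.20-fold. Crybb2 was not called (log2 -0.86, edgeR adjusted p 0.118) and had 3.09 ± 1.63 CPM in the knockout and 5.88 ± 1.46 CPM in the wild type. The gamma crystallin genes are close copies of one another, so the division of reads among them is uncertain, and Cryga shares 47.9% of its exon bases with Gm28845 on the same strand. The list lay lower than other genes (camera adjusted p 1.4e-11), with adjusted p = 0.68 with an estimated correlation, and fry gave an adjusted p of 0.013.

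Fibre genes other than crystallins, among them genes for membrane, junction and filament proteins, fell along with the crystallins. Of 18 tested members, 15 fell and 0 rose by edgeR, also adjusted over the list alone, and the median log2 change was -3.22. By limma-voom 12 fell and 0 rose, by DESeq2 15 fell and 0 rose, and none rose at an unadjusted edgeR p below the threshold. In order of size the decreases were led by Lctl, Dnase2b, Birc7 and Bfsp1. Lctl had 0.0615 ± 0.0539 CPM in the knockout and 8.98 ± 7.44 CPM in the wild type and did not pass by limma-voom (adjusted p 0.0541). Its log2 change was -7.68, and between -8.30 and -6.49 without 1 library. The water channel gene Mip fell 13.3-fold, from 4081 ± 1180 to 307 ± 104 CPM, though 57% of its exon bases are shared with Gm26847 on the opposite strand. The beaded filament gene Bfsp2 fell 10.4-fold, from 308 ± 156 to 29.7 ± 2.94 CPM. Lim2 and Caprin2 each fell 10.3-fold. Cdh2 (log2 -0.14), Fabp5 (-0.06) and Hspb1 (0.70) were not called, with edgeR adjusted p of 0.352, 0.772 and 0.283. Lgsn and Lenep had too few counts to be tested. The camera adjusted p was 5.5e-10, with adjusted p = 0.68 with an estimated correlation, and the fry adjusted p was 0.013. The calls of both lists stayed at 15 whichever library was left out.

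Genes of the lens epithelium, the proliferating cell layer that covers the fibres, moved in both directions. Of 11 tested, 6 rose, 3 fell and 2 were not called, and the same numbers held adjusted over the list alone. The gap junction gene Gja1 rose 2.43-fold (log2 1.28, SE 0.166, edgeR adjusted p 0.000984), from 299 ± 68.1 to 729 ± 30.8 CPM. The Wnt antagonist gene Sfrp1 fell 2.23-fold (log2 -1.16, SE 0.143, edgeR adjusted p 0.000799), from 1856 ± 258 to 833 ± 69.5 CPM. Pdgfra rose by 0.80 on the log2 scale and Wls by 0.75, while Aldh1a1 fell by 0.73 and Cdh1 rose by 0.70. Foxe3, a transcription factor gene of epithelial cells, fell by 0.62 (edgeR adjusted p 0.0271), a call lost without wild type library 2 (0.0619) or 3 (0.0856). Pax6 rose by 0.46 (edgeR adjusted p 0.0225), a call lost without wild type library 2 (0.116) or 3 (0.0875). Sparc (log2 -0.16) and Npnt (-0.02) were not called. The list as a whole was not called (median log2 0.31, camera adjusted p 0.35).

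Among lens transcription factors, Hsf4, a heat shock factor gene of maturing fibres, had by far the largest decrease. It fell 11.9-fold (log2 -3.57, SE 0.317, edgeR adjusted p 0.000195), from 129 ± 46.6 to 11.2 ± 2.90 CPM. Of 16 tested factors, 4 rose, 6 fell and 6 were not called, and 5 rose and 7 fell adjusted over the list alone. Mafg fell by 1.16, Meis1 rose by 0.92 and Gata3 by 0.83, and Maf, which activates crystallin genes, fell by 0.77. The call of Maf was lost without knockout library 3 (edgeR adjusted p 0.0565), wild type library 2 (0.0735) or wild type library 3 (0.0674). Tfap2a rose by 0.71, a call lost without wild type library 2 (0.0703). Hey1 fell by 0.66. Six3 (log2 0.16) and Meis2 (0.02) were not called. Sox1 and Sox2 were listed at 0 counts in every library although neighbouring noncoding genes at both loci had counts, so their levels could not be read. The numbers were 2 rising and 3 falling without wild type library 2, and 3 and 3 without wild type library 3. As a whole the list was not called (camera adjusted p 0.34), with a median log2 change of -0.30.

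FGF signalling drives fibre differentiation, and its receptor gene Fgfr3 fell 9.26-fold while several genes induced by the pathway rose. Fgfr3 went from 298 ± 78.2 to 32.4 ± 6.01 CPM (log2 -3.21, SE 0.229, edgeR adjusted p 0.000104), and Fgfrl1 fell 4.37-fold. The transcription factor gene Etv4 rose by 1.08, the feedback gene Il17rd by 0.98, Dusp6 by 0.87 (edgeR adjusted p 0.0015, from 60.3 ± 8.13 to 110 ± 11.1 CPM) and Spred3 by 0.85. The call of Il17rd was lost without wild type library 2 (0.0556) or 3 (0.0501). Fgfr1 (log2 0.21, edgeR adjusted p 0.10) and Fgfr2 (0.31, 0.0533) were not called, nor were Spry1 (0.20), Spry2 (-0.35), Spry4 (0.20) and Etv5 (-0.37). With upper quartile scaling Fgfr1 (0.0486) and Fgfr2 (0.0307) passed, Fgfr2 also passed with a filter of 1 CPM (0.0461) or limma-voom (0.0487), and Etv5 passed with DESeq2 (0.0316) or no filter (0.0377). Fgfr2 passed without wild type library 3 (0.0426), Spry2 without wild type library 1 (0.0115) and Etv5 without knockout library 2 (0.0472) or wild type library 1 (0.0161). Of 17 tested members 7 rose, 2 fell and 8 were not called, and 8 rose and 4 fell adjusted over the list alone. It was 4 members that fell when wild type library 1 was left out. The list was not called by camera (adjusted p 0.12, median log2 0.31, mean 0.05), while fry gave an adjusted p of 0.023.

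In the Notch pathway, which keeps lens epithelial cells in cycle, the receptor genes Notch1 and Notch2 rose and Jag1, the ligand gene of fibre cells, fell. Of 14 tested members, 3 rose, 3 fell and 8 were not called, and 5 rose and 3 fell adjusted over the list alone. Notch2 rose by 1.23 (edgeR adjusted p 0.019), a call lost without wild type library 2 (0.0845) or 3 (0.0645). Lfng fell by 1.17 (edgeR adjusted p 0.000539), from 68.6 ± 9.17 to 30.5 ± 3.82 CPM. Notch1 rose by 0.79 (edgeR adjusted p 0.0364), a call lost without knockout library 2 (0.0831) or 3 (0.10) or wild type library 2 (0.122) or 3 (0.133). The receptor gene Notch3 was not called (log2 0.48, edgeR adjusted p 0.108) and passed without knockout library 1 (0.013). The target gene Hes1 rose by 0.76, Jag1 fell by 0.76, from 467 ± 69.2 to 276 ± 38.4 CPM, and Hey1 fell by 0.66. The rising members numbered 1 without wild type library 2 or 3, and 5 without wild type library 1. Camera gave an adjusted p of 0.34 for the list.

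The CDK inhibitor gene Cdkn1c, which is switched on as fibre cells leave the cycle, fell 2.26-fold. Cdkn1c went from 1108 ± 169 to 490 ± 23.6 CPM (log2 -1.18, SE 0.137, edgeR adjusted p 0.000595), with 30.7% of its exon bases shared with Gm44732 on the opposite strand. It was the 1 called member of 7 tested CDK inhibitor genes, also adjusted over the list alone. No inhibitor gene rose by edgeR, DESeq2 or limma-voom, adjusted or not. Cdkn1b (log2 -0.28, edgeR adjusted p 0.135) and Cdkn1a (-0.42, 0.34) were not called, though Cdkn1b passed without wild type library 1 (0.0308) and Cdkn1a without wild type library 3 (0.0366). When wild type library 1 or 3 was left out, 3 members fell. The list had a camera adjusted p of 0.15, and of 0.027 without wild type library 3.

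Of 26 proliferation genes, 14 rose, 0 fell and 12 were not called by edgeR, and 19 rose and 1 fell adjusted over the list alone. The increases were small, with a median log2 change of 0.41. The summed list had 5001, 4592 and 4730 CPM in knockout libraries 1, 2 and 3 and 4412, 3976 and 3717 CPM in the wild type libraries, and the neural retina markers were higher beside it, with sums of 888, 791 and 771 CPM and 612, 393 and 403 CPM. The 3 largest were those of E2f1 (log2 0.60, edgeR adjusted p 0.00878, from 26.1 ± 1.97 to 39.5 ± 5.45 CPM), Rrm2 (0.59, 0.0108) and Ccnb2 (0.56, 0.0128). Mki67 rose by 0.56 (edgeR adjusted p 0.0297), from 373 ± 64.1 to 550 ± 87.9 CPM. Ccnd2 was not called (log2 -0.35, edgeR adjusted p 0.0857) and was the 1 member lower at an unadjusted p and by DESeq2 (0.033). By limma-voom 15 members rose and 0 fell, and by DESeq2 17 rose and 1 fell. These calls depended on single libraries, while the sizes of the largest changes moved less. Without 1 library, the log2 change lay between 0.48 and 0.69 for E2f1, 0.49 and 0.67 for Rrm2 and 0.44 and 0.64 for Ccnb2. Without knockout library 1, 9 rose, without knockout library 2, 7 rose, and without wild type library 3, 1 rose. Without wild type library 2 no member was called by edgeR, with 10 higher at an unadjusted p. Without wild type library 1, 16 rose. The call of E2f1 was lost without wild type library 2 (0.052), that of Rrm2 without wild type library 2 (0.0598) or 3 (0.0563) and that of Ccnb2 without wild type library 2 (0.066) or 3 (0.0628). Mki67 was not called without knockout library 2 (0.0513) or 3 (0.0782) or wild type library 2 (0.132) or 3 (0.104). The list lay higher than other genes (camera adjusted p 3.6e-05, between 2.3e-06 and 0.00072 without 1 library), with adjusted p = 0.68 with an estimated correlation and 0.08 by fry.

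Targets of p53 and genes of apoptosis showed no shared direction. Of 16 tested, 2 rose, 2 fell and 12 were not called, also adjusted over the list alone. Aen fell by 1.14 (edgeR adjusted p 0.00028), from 68.1 ± 4.0 to 30.8 ± 3.69 CPM, and Ccng1 fell by 1.00, from 131 ± 21.1 to 65.6 ± 5.80 CPM. The death gene Bcl2l11 rose by 0.70 (edgeR adjusted p 0.00115). The rising members numbered 1 without wild type library 3. Bax (log2 -0.02) and Mdm2 (-0.20) were not called. The median log2 change of the list was 0.02, the mean was -0.15, and camera gave an adjusted p of 0.77 in the direction of the mean.

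Cell adhesion and cytoskeleton genes fell more often than they rose, with junction and integrin genes among those that fell. Nrcam fell 7.40-fold (log2 -2.89, edgeR adjusted p 0.000181), from 464 ± 104 to 63.1 ± 19.2 CPM. The desmosome gene Dsp rose by 2.11 (edgeR adjusted p 0.0306), a call lost without knockout library 3 (log2 1.23, adjusted p 0.0805) or wild type library 2 (0.0979) or 3 (0.0787). Its counts, 570, 164 and 552 in knockout libraries 1, 2 and 3 and 199, 42 and 130 in the wild type libraries, moved with those of the surface ectoderm marker Krt5, 786, 132 and 568 and 182, 32 and 119. Ctnna2 fell by 1.97, Pkp2 by 1.33, Itga6 by 1.23, Ank2 by 1.03 and Ezr by 0.85, and Itga5 rose by 0.80. Actb (log2 0.07), Ctnnb1 (0.10) and Cdh2 (-0.14) were not called. Of 22 tested members, 4 rose, 10 fell and 8 were not called, and 5 rose and 11 fell adjusted over the list alone. The rising members numbered 2 without wild type library 2 or 3. The camera adjusted p was 0.024, with adjusted p = 0.68 with an estimated correlation, and the fry adjusted p was 0.012.

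Among matrix genes, Tnc, Vcan, Tgfbi and Nid2 rose and Col4a2, Col4a1 and Nid1 fell. Beside Tnc, the proteoglycan gene Vcan rose 4.93-fold (log2 2.30, SE 0.248, edgeR adjusted p 0.000416), from 48.6 ± 18.6 to 240.0 ± 22.5 CPM. Tgfbi rose by 1.85 (edgeR adjusted p 0.0243), a call lost without wild type library 2 (0.0924) or 3 (0.0859) or with limma-voom (0.0649), and its log2 change was 0.96 without knockout library 3. In that library the summed periocular mesenchyme markers had 3614 CPM, against 1234 and 846 CPM in knockout libraries 1 and 2 and at most 669 CPM in the wild type. Nid2 rose by 1.72. The lens capsule collagen genes Col4a2 and Col4a1 fell by 0.90 and 0.87. Nid1 fell by 0.74, a call lost without wild type library 2 (0.0788) or 3 (0.0767). Fn1 was not called (log2 0.92, edgeR adjusted p 0.123) and had 557 ± 353 CPM in the knockout and 294 ± 107 CPM in the wild type, and it passed without knockout library 1 (0.0435) or with no filter (0.0444). Its log2 change was 0.27 without knockout library 3. Of 17 tested members, 4 rose, 3 fell and 10 were not called, and 5 rose and 4 fell adjusted over the list alone. Without knockout library 1, 8 members rose. The list was not called by camera (adjusted p 0.34, median log2 0.29).

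Genes of the mesenchymal transition list, which mark cells that leave an epithelial state, included S100a4, which fell by 4.05, and 4 genes that rose. The change of S100a4 was -3.35 without knockout library 1 and -5.12 without knockout library 3. S100a4 shares 51.7% of its exon bases with Gm42674 on the same strand. Col1a1 rose by 2.62 (edgeR adjusted p 0.0256), a call lost without knockout library 3 (log2 1.38, adjusted p 0.056), wild type library 1 (0.0615) or wild type library 2 (0.0979). The smooth muscle actin gene Acta2 rose 3.82-fold (edgeR adjusted p 8.3e-05), from 8.62 ± 0.917 to 32.9 ± 2.32 CPM. Tgfbi rose by 1.85 and by 0.96 without knockout library 3, a call lost without wild type library 2 (0.0924) or 3 (0.0859) or with limma-voom (0.0649). Snai2 rose by 0.98, a call lost without wild type library 2 (0.0705) or 3 (0.0617). Zeb1 (log2 0.15) and Zeb2 (0.04) were not called. Of 12 tested members 4 rose, 1 fell and 7 were not called, and 6 rose and 1 fell adjusted over the list alone. With wild type library 2 left out 1 rose, and with wild type library 3 left out 2 rose. The list's camera adjusted p was 0.024, with adjusted p = 0.68 with an estimated correlation, and it was 0.079 without knockout library 3. Markers of periocular mesenchyme, which share Col1a1 and Twist1 with this list, summed to 3614 CPM in knockout library 3, against 1234 and 846 CPM in knockout libraries 1 and 2.

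Genes tied to Prox1 in lymphatic endothelium, where Prox1 sets cell identity, were not called as a list. Of 9 tested, 3 rose, 1 fell and 5 were not called, also adjusted over the list alone. Angpt2 fell by 1.49 at a low level, from 1.14 ± 0.209 to 0.361 ± 0.148 CPM, a call lost without knockout library 2 (0.0646), knockout library 3 (0.0513) or wild type library 2 (0.0806), and with DESeq2 (0.0515). Reln rose 2.49-fold (edgeR adjusted p 0.00321), from 44.2 ± 9.78 to 110 ± 31.7 CPM. Nr2f2 rose by 0.67 (edgeR adjusted p 0.0315) and was called in 1 of the 6 fits without a library. Its adjusted p was 0.063, 0.0621 and 0.0684 without knockout library 1, 2 and 3, and 0.109 and 0.114 without wild type library 2 and 3. Pdpn rose by 0.52, a call lost without knockout library 2 (0.0658) or wild type library 2 (0.0956). Flt4 (log2 0.37) and Lyve1 (-0.15) were not called, though Flt4 passed without wild type library 1 (0.045). Without knockout library 2 or wild type library 2, 1 member rose and none fell, and without wild type library 1, 5 rose. By camera the adjusted p of the list was 0.27.

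**Figure D2:**
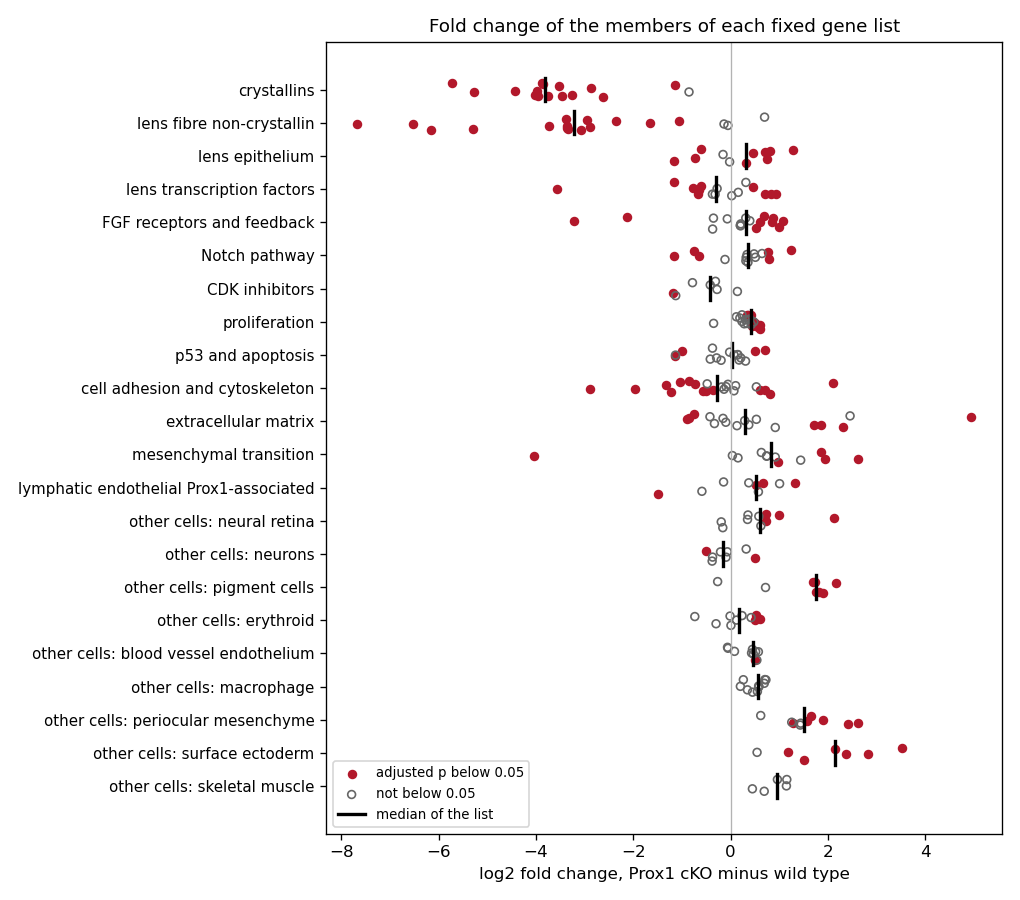
Log2 fold change, knockout minus wild type, of each tested member of the gene lists, 1 point per gene, with filled red points for an edgeR adjusted p below the threshold of 0.05, open points for the rest and a black bar for the median. Crystallins have a median of -3.81 and the other fibre genes -3.22, while the proliferation genes have a median of 0.41.

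Pigment cell, surface ectoderm and periocular mesenchyme markers, from tissues that border the lens, were higher in the knockout libraries. The summed pigment markers had 382, 280 and 768 CPM in knockout libraries 1, 2 and 3 and 206, 90.2 and 183 CPM in the wild type libraries. The summed mesenchyme markers had 1234, 846 and 3614 CPM in the knockout and 669, 318 and 585 CPM in the wild type, and the ectoderm markers 71.5, 39.5 and 134 CPM and 29.2, 10.1 and 20.8 CPM. Knockout library 3 was the highest for all 3 lists, and it was also the highest for the mesenchymal transition list. Among pigment markers 6 of 8 rose, also adjusted over the list alone, led by Tyr (log2 2.17), Pmel (1.90), Tyrp1 (1.82) and Dct (1.75). The call of Tyr was lost without wild type library 2 (0.0591) or 3 (0.0536), and that of Tyrp1 without wild type library 2 (0.0812) or 3 (0.0541). Among mesenchyme markers 6 of 10 rose, and 9 adjusted over the list alone, led by Col1a1 (2.62), Kera (2.40) and Col1a2 (1.90). Col1a1 was not called without knockout library 3 (0.056) or wild type library 1 (0.0615) or 2 (0.0979). Kera was not called without knockout library 1 (0.0761) or 3 (0.0884) or wild type library 1 (0.0862) or 2 (0.122) or with DESeq2 (0.0536), and Col1a2 without knockout library 3 (0.0576) or wild type library 2 (0.106) or 3 (0.0601). Without knockout library 3 the log2 changes were 1.38 for Col1a1, 1.04 for Col1a2, 1.45 for Tyr and 1.17 for Tyrp1, and that of Kera was 3.90 without wild type library 3. Among ectoderm markers 6 of 7 rose, also adjusted over the list alone, led by Krt14 (3.53, edgeR adjusted p 0.00169), with 66, 16 and 33 counts in the knockout and 2, 5 and 3 in the wild type. Krt15 rose by 2.83, and by 2.22 without knockout library 3, a call lost without wild type library 2 (0.0608). The camera adjusted p was 0.02 for pigment cells, 0.0037 for mesenchyme and 0.01 for ectoderm, each with adjusted p = 0.68 with an estimated correlation. Without knockout library 3, the camera adjusted p for pigment cells was 0.069, Mitf fell (adjusted p 0.0166), and 1 mesenchyme and 3 ectoderm markers rose. Without wild type library 2, 3 pigment and 2 ectoderm markers rose and no mesenchyme marker was called by edgeR, with 8 higher at an unadjusted p. With wild type library 3 left out, 3 pigment, 2 mesenchyme and 3 ectoderm markers rose.

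Neural retina markers lay somewhat higher in the knockout, and neuron, blood, vessel, macrophage and muscle markers gave few calls. Of 10 retina markers 4 rose, also adjusted over the list alone, among them Rlbp1 (log2 2.13), Sox11 (0.99) and Six6 (0.72). Without knockout library 1 or wild type library 2 or 3, 2 retina markers rose, and Six6 (0.0774, 0.116 and 0.106) was not called. Six6 was also not called without knockout library 2 (0.054). The camera adjusted p of the retina list was 0.048, with adjusted p = 0.68 with an estimated correlation, and it was 0.14, 0.055 and 0.062 without knockout library 1, wild type library 2 and wild type library 3. With upper quartile scaling it was 0.067, and with a filter of at least 1 CPM in 3 libraries 0.051. Among 8 neuron markers Syt1 rose by 0.51 and Elavl4 fell by 0.50 (camera adjusted p 0.77), also adjusted over the list alone. Syt1 was not called without knockout library 2 (0.0923) or 3 (0.0682) or wild type library 2 (0.112) or 3 (0.127), nor with no filter (0.0553). Elavl4 was not called without knockout library 2 (0.119) or 3 (0.0961) or wild type library 1 (0.0538) or 2 (0.131), nor with upper quartile scaling (0.0571) or limma-voom (0.0593).

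Of 10 erythroid markers 3 rose, and 2 adjusted over the list alone, led by Hba-a1 (log2 0.60, edgeR adjusted p 0.0486), while Hbb-y, an abundant embryonic globin gene, was not called (log2 0.12, and 0.75 without wild type library 1). Hba-a1 was not called without knockout library 1 (0.0719), 2 (0.105) or 3 (0.0995) or wild type library 2 (0.178) or 3 (0.167). The camera adjusted p of the erythroid list was 0.26, and it was 0.015 without wild type library 1. Of these markers 1 rose without knockout library 3 or wild type library 2. No erythroid marker was called by edgeR without knockout library 2, with 3 higher at an unadjusted p, or without wild type library 3, with 2 higher and 1 lower at an unadjusted p. Of 10 vessel markers Cldn5 rose by 0.51 (edgeR adjusted p 0.0442) and 9 were not called, with 0 rising by edgeR adjusted over the list alone, 4 at an unadjusted p and 3 by DESeq2. Cldn5 was not called without knockout library 1 (0.0778) or 2 (0.147) or wild type library 2 (0.164) or 3 (0.162). Without wild type library 1, 7 vessel markers rose and the camera adjusted p went from 0.11 to 0.015. Of 10 macrophage markers 0 changed by edgeR, with 0 adjusted over the list alone, 1 higher at an unadjusted p, 1 rising by DESeq2 and 0 by limma-voom. The highest log2 change among them was that of Adgre1, listed as Emr1 (0.72, edgeR adjusted p 0.142). The camera adjusted p of the macrophage list was 0.05, which did not pass, and it was 0.027, 0.0075 and 0.032 without knockout library 1, wild type library 1 and wild type library 2. It also passed with DESeq2 size factors (0.046) and with no filter (0.027). Of these markers 4 rose without wild type library 1. Of 5 tested skeletal muscle markers 0 changed by edgeR, DESeq2 or limma-voom, adjusted or not, and 0 adjusted over the list alone (camera adjusted p 0.65), and Myh3 had 9.12 ± 13.6 CPM in the knockout and 3.94 ± 4.29 CPM in the wild type. The log2 change of Myh3 was 1.15 with all libraries, -1.77 without knockout library 3, 1.75 without knockout library 1 and 2.52 without wild type library 3.

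**Figure D3:**
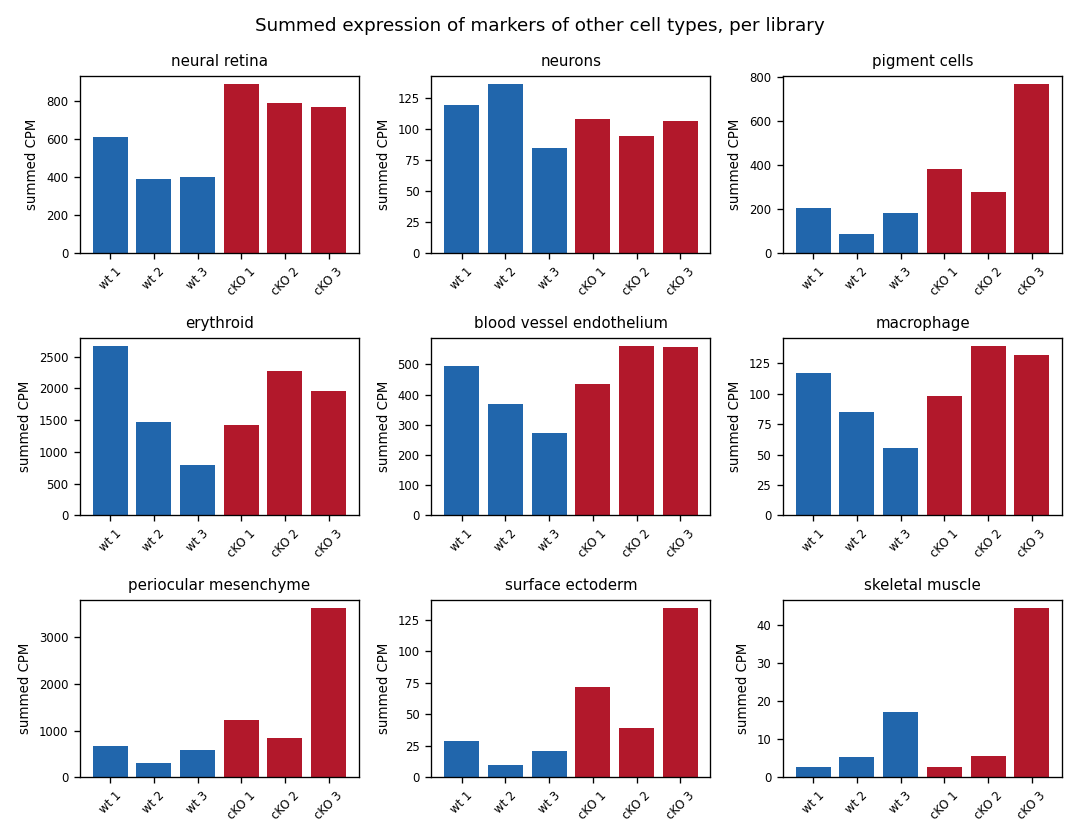
Summed TMM-scaled CPM of the markers of 9 other cell types, 1 bar per library, for the 3 knockout and the 3 wild type libraries. Periocular mesenchyme markers reach 3614 CPM in knockout library 3 and between 318 and 669 CPM in the wild type libraries.

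Of the genes fixed as checks, Bfsp2 is among the fibre genes that fell, so its level could not serve as a check of strain. Nnt and Wdfy1, which differ between some mouse strains, were not called. Nnt had 107 ± 3.35 CPM in the knockout and 106 ± 2.82 CPM in the wild type (log2 0.01, edgeR adjusted p 0.952), and Wdfy1 had 71.3 ± 0.748 and 64.7 ± 0.837 CPM (log2 0.14, edgeR adjusted p 0.195), with every knockout library above every wild type library. Xist, expressed from the inactive X chromosome of females, had 16.6 ± 2.96 and 12.1 ± 6.27 CPM (edgeR adjusted p 0.391). Xist and the Y-linked genes were detected in every library. In wild type libraries 1, 2 and 3, Xist had 346, 87 and 255 counts and Ddx3y had 702, 1225 and 778. The labels do not give the sex of the lenses, so an unequal share of males between pools can not be told apart from other effects. The Y-linked gene Eif2s3y fell by 1.38 (edgeR adjusted p 0.0146), a call lost without wild type library 2 (0.0591). Ddx3y (log2 -0.75, edgeR adjusted p 0.0574), Uty (-0.74, 0.0796) and Kdm5d (-0.59, 0.107) were not called. Without knockout library 3 these 3 genes passed (0.0437, 0.0229 and 0.017), and without wild type library 1 Ddx3y (0.0133) and Uty (0.0387) passed. With no filter Ddx3y (0.0128), Uty (0.0225) and Kdm5d (0.0447) passed, and with DESeq2 Ddx3y (0.0115) and Uty (0.0233) did.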

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

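The comparison of groups in this part was chosen only after values had been seen. It concerns the 13 pairs of features that were left out because a count and its CPM belonged to different members of the pair. The sum of both members does not depend on which member a count belongs to, so the sum was compared between the groups, in CPM scaled by TMM. In 3 of the 13 pairs every knockout library lay above every wild type library, which chance gives for 5% of pairs. In either direction 4 pairs (30.8%) were apart, a lower share than the 50.1% of all tested genes, so the pairs do not stand out from other genes. The catenin gene pair under Ctnnd1, a gene for a protein that binds cadherins at cell junctions, had 45.1 ± 2.74 CPM in the knockout and 38.4 ± 2.77 CPM in the wild type (SD, n = 3 each), a ratio of 1.17. The pair under Fmn1, a formin gene, had 5.32 ± 0.946 and 2.0 ± 0.47 CPM, a ratio of 2.67. The pair under Sema6c, a semaphorin gene, had 2.74 ± 0.54 and 1.72 ± 0.349 CPM, a ratio of 1.59. In 1 pair, under the kinase gene Csnk2a1, every knockout library lay below every wild type library, with 137 ± 14.7 and 180 ± 13.6 CPM. These sums cannot say which member of a pair differed, and no explanation was tested for them.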

How the results depend on the processing

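The settings without knockout library 3 and wild type library 1 together and without Lars2 and Gm26917 were chosen only after the data had been seen. There were 18 alternatives. The count of 4659 changed genes lay between 4176 and 5334 under the alternatives other than leaving out a single library, and between 2267 and 5317 when 1 library was left out, with 2267 without wild type library 2 and 2475 without wild type library 3. Changes of at least 2-fold were 1565, and between 1048 and 1956 without 1 library. With all libraries more of these were higher than lower (836 and 729), but fewer were without wild type library 2 (427 and 621), wild type library 3 (525 and 620) or knockout library 3 (564 and 769), and with knockout library 3 and wild type library 1 out together (912 and 972). No gene called in both fits had opposite signs. Scaling moved the median of all genes by at most 0.049 on the log2 scale, under upper quartile scaling, where 4744 genes were called and 54.9% of them rose, against 48.6%. DESeq2 called 4833 genes and limma-voom 4603. With replicate number as a replicate block, 4176 genes were called and 1487 at least 2-fold. The labels do not say whether equal numbers pair the libraries. Deviations of libraries of the same number correlated at -0.03, 0.25 and 0.11 across genes, and those of different numbers between -0.22 and 0.09. These few values do not decide whether the libraries are paired. Prox1 stayed lower and past the threshold under all alternatives run on it. With an estimated correlation the adjusted p was 0.68 for crystallins, for the other fibre genes, for proliferation, for cell adhesion and for mesenchymal transition alike. That test allows for the correlation between members, which was estimated at 0.767 for crystallins and 0.649 for the other fibre genes. Lists with little estimated correlation had the same adjusted p of 0.68, such as cell adhesion (0.06) and the FGF list (-0.008). The value therefore does not tell these lists apart. By fry, adjusted p was 0.023 for the FGF list, 0.08 for proliferation and 0.08 for mesenchymal transition. Without 1 library, the camera adjusted p lay between 0.027 and 0.26 for CDK inhibitors and between 0.01 and 0.079 for mesenchymal transition. With knockout library 3 and wild type library 1 out together, a pair of muscle genes reversed, Myh3 to -2.338 (adjusted p 0.0379, from 1.15) and Myh8 to -3.331 (0.0324, from 0.96). Most of the counts of Myh3 lay in knockout library 3 (246) and wild type library 3 (153). Except for the construction of each test, the cause was not tested. Among the other single genes and marker lists, 4664 values kept direction and side of the threshold, 202 gained a call and 227 lost one. Depth limits genes near 3 counts, which is between 0.106 and 0.33 CPM.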

Other observations

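The gene families, the genes outside the fixed lists and all tests in this part except the splits of the libraries were chosen only after the results had been seen.

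With genes grouped by the root of their symbols, most genes with Eif and Ndufa symbols were lower in the knockout. The fall was not particular to them. Among other families, 15 of 46 Rpl genes fell (camera adjusted p 1.1e-05), 14 of 47 Mrpl genes (9.2e-05), 7 of 14 Psmd genes (0.0024) and 9 of 23 Cox genes (0.019). In each of these families 0 rose, and the camera adjusted p with an estimated correlation was 0.84. Of 53 tested genes with Eif symbols, which are mostly those of translation initiation factors, 31 fell and 1 rose, with a median log2 change of -0.40 (camera adjusted p 5e-06 over 152 families, and 0.84 with an estimated correlation). The 53 also include kinase genes (Eif2ak1 to Eif2ak4), binding protein genes such as Eif4ebp1, a pseudogene and the Y-linked Eif2s3y, whose level depends on the sex of the pools, and the 1 that rose is the kinase gene Eif2ak3. Eif5b fell by 1.29, from 537 ± 190 to 220 ± 8.33 CPM (SD, n = 3 each), and Eif2s1 fell by 0.88, from 213 ± 33.4 to 116 ± 10.1 CPM. The falling members numbered 18 without knockout library 2, 20 without knockout library 3, 14 without wild type library 2 and 15 without wild type library 3, and Eif2ak3 was not called without knockout library 2 or wild type library 2 or 3. Of 14 Ndufa genes, most of them for subunits of respiratory complex I, 11 fell and 1 rose (camera adjusted p 0.004, and 0.84 with an estimated correlation), and Ndufa1 fell 2.35-fold, from 270 ± 70.6 to 115 ± 24.9 CPM. Without knockout library 2 or 3 or wild type library 2, 7 Ndufa genes fell, and without wild type library 3, 6 fell. The rising Ndufa4l2 was not called without these libraries (0.0694, 0.0748, 0.103 and 0.108). The medians of the Eif and Ndufa genes kept their sign under every scaling.

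The Wnt receptor, semaphorin, Sox and collagen families were higher by camera only with its preset correlation. With an estimated correlation the adjusted p was 0.84 for each. The Eif and Ndufa families had the same value, so it does not tell these families apart. Of 10 tested Fzd genes 6 rose (camera adjusted p 0.019, estimated 0.84), with 5 rising under DESeq2 size factors, and Fzd1 and Fzd2 rose 2.04-fold and 2.03-fold. The rising Fzd genes numbered 3 without wild type library 2 or 3. Of 19 Sema genes 7 rose and 12 were not called (camera adjusted p 0.004, estimated 0.84), and 4 without wild type library 2, with Sema3f and Sema6a 3.09-fold and 2.47-fold higher. Of 16 Sox genes and transcripts 8 rose and 2 fell (camera adjusted p 0.019, estimated 0.84). Among the 8 was Sox11, a member of the neural retina marker list, which also lay somewhat higher in the knockout. Sox9 rose 4.42-fold, from 10.8 ± 0.395 to 47.8 ± 10.4 CPM, Sox4 rose 2.12-fold and the noncoding gene Sox2ot fell 2.24-fold, from 145 ± 34 to 64.6 ± 5.30 CPM. Of 40 genes with Col symbols, all collagen genes but Col4a3bp, 22 rose and 4 fell (camera adjusted p 0.004, estimated 0.84). The periocular mesenchyme markers, which include Col1a1, Col1a2 and Col3a1, moved with them and summed to 1234, 846 and 3614 CPM in knockout libraries 1, 2 and 3 and 669, 318 and 585 CPM in the wild type libraries. Only 8 collagen genes rose without knockout library 3, 7 without wild type library 2 and 10 without wild type library 3. Col13a1 rose 3.04-fold with little spread, from 29.0 ± 1.94 to 88.1 ± 1.47 CPM, and Mmp14 rose 3.10-fold. The fibre protease gene Capn3 fell 7.98-fold, from 8039 ± 1600 to 1007 ± 213 CPM. The imprinted RNA gene H19 rose 1.49-fold, from 5472 ± 391 to 8146 ± 362 CPM (edgeR adjusted p 0.0155), a call lost without knockout library 2 (0.0663) or wild type library 3 (0.0831).

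Lars2 took 0.676, 5.71 and 7.05% of the counts in knockout libraries 1, 2 and 3 and 1.74, 0.969 and 0.878% in the wild type libraries, and was not called (edgeR adjusted p 0.105). It passed without knockout library 1 (0.00237). Gm26917 had its highest shares in the same libraries and was not called either (0.096, and 0.00422 without knockout library 1). Of 95 tested genes within 10 Mb of Prox1, 38.9% were called, against 32.6% elsewhere (Fisher's exact test, p = 0.189, two-sided).

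The split of the 6 libraries into knockout and wild type gave 4659 changed genes and 1565 changed at least 2-fold by edgeR. The highest of the other splits gave 0 for both, with between 41 and 737 genes at an unadjusted p below the threshold. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

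Wild type library 1 was lower than both other wild type libraries in 31 of 31 crystallin and fibre genes of at least 10 CPM, with a median log2 ratio of -1.04 to their mean. The ratio was 1.74-fold for Cryaa, 5.56-fold for Bfsp1, 10.4-fold for Birc7 and 16.5-fold for Dnase2b, and 1.13-fold for Cdh2. Dilution by tissue other than lens would lower genes expressed only in the lens by 1 factor. The interquartile range of the log2 ratios was 0.61, which argues against dilution as the whole cause. Whether other tissues express these genes was not tested. Among wild type libraries, library 1 had the highest retina (612 CPM, against 393 and 403) and vessel marker sums (494, against 369 and 274). It was also the highest for pigment, erythroid, macrophage, mesenchyme and ectoderm markers, but not for neuron and muscle markers. Dilution as a part of the cause therefore stays open. Knockout RNA mixed into the library would imply a share of 0.56 from the fibre genes and of 0.08 from 79 genes at least 4-fold higher in the knockout, called in a fit without this library, a difference of -0.48, which argues against a mixture as the whole cause (a first form of this test used another set of increased genes). At 2-fold in that fit, the median share was 0.23 for 496 higher genes (quartiles 0.10 and 0.38) and 0.44 for 639 lower genes (0.35 and 0.55). These ranges overlap. The 79 genes at least 4-fold higher had quartiles of 0.01 and 0.17, against 0.49 and 0.66 for the fibre genes. In the 10 named increased genes, which were chosen with this library in the fit, the share lay between -0.013 and 0.019. A mixture would give all genes the same share, so it stays open only as a small part of the cause. No label gives a difference in stage or handling, so no biological explanation was tested, and what sets this library apart stays open.

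Of the 836 genes at least 2-fold higher, the 818 that are not among the markers used may in part come from neighbouring tissue, since pigment, mesenchyme and ectoderm markers were higher too. Within the groups, the slopes of these genes on the mean of the 18 called markers had an upper quartile of 0.46. The lower quartile of the markers' own slopes was 0.77. The markers form this mean themselves, so their slopes are high by construction and part of the gap is built in. The test therefore does not decide whether these tissues are the source of the set. In the set, 91 genes had slopes that reached 0.77, while the 10 named increased genes had a median slope of -0.05. In an earlier form of the test, on knockout library 3 over the other knockout libraries, 130 genes reached the markers' lower quartile of 0.99. RNA from vessels, blood, macrophages or neurons would have to raise their markers at least 2-fold too, a log2 change of 1. The upper quartile was 0.51, 0.48, 0.66 and 0.03 for these markers and at most 0.91 without 1 library, which argues against these cells as the source of the set as a whole. Single markers reached 1 only without wild type library 1, 1 of blood and 2 of macrophages. Retina RNA stays open as a source, since the retina marker Rlbp1 rose by 2.13 although the upper quartile of the retina markers was 0.73. How many of all these markers lens cells express was not tested. In an earlier form of this test the changes of the 818 genes were set against the markers, which decided nothing because these genes were chosen by their change.

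Among lens epithelium genes, 6 rose and 3 fell. A lower share of fibre RNA alone would raise the epithelium genes together. The 3 that fell, Sfrp1, Aldh1a1 and Foxe3, went against it as the whole cause, but they are part of the pattern itself and were no separate test. Foxe3 lost its call without wild type library 2 (0.0619) or 3 (0.0856), while Sfrp1 and Aldh1a1 kept theirs. A different share of fibre cells together with regulation by Prox1 within cells stays open, since the libraries hold whole lenses.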
